A study of Caenorhabditis elegans with 9 samples.

How the data were processed

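Nuclear RNA of whole adult *C. elegans* of strain JK560 was measured in 9 droplet libraries with unique molecular identifiers (UMIs), 5 from unexposed P0 animals, 2 from F1 animals of a water group and 2 from F1 animals of a 0.05% ethanol group. Per the labels, animals were moved from 20 to 25 °C and collected on day 2 of adulthood. The treatment protocol in the labels gives 62 h at the higher temperature, and the growth protocol gives a shorter time, so the length is open. All 9 libraries carry the same protocol text.

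The deposited matrices hold whole-number UMI counts per gene and barcode, made by the authors with Cell Ranger against genome build ce10, per the submitters' processing notes, and the matrix header gives software version 3.0.2. No normalization had been applied to the deposited counts. Parameters of that step, the gene annotation and any removal of free RNA are not given in the sources used here. Each library lists 46904 genes, and the smallest barcode total was 500 UMIs in most libraries, so a depth limit had acted before deposit. Gene symbols are those the files pair with the identifiers. A gene table of assembly WBcel235 was used for the order of neighbouring genes only, with 99.8% of identifiers matched, and no coordinates are given because the builds differ.

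Before the data were examined, the groups, tests, gene lists, cell type markers, rule for naming genes and processing alternatives were fixed. Barcodes with at least 200 genes detected and at most 20% of UMIs from mitochondrially encoded genes were kept, which left 19360 of 19367. Per library this gave 1116 to 3411 nuclei, with 4014584 to 10729660 UMIs in them. Doublets were kept: Scrublet with its automatic threshold marked 20 nuclei, too few to have worked, and removal at 0.8% per 1000 nuclei was an alternative. Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes ranked per library, 50 principal components and 15 neighbours gave 24 Leiden clusters at resolution 1, with no integration of libraries (scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15).

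A cluster was called like a cell type from the fixed markers. It needed at least 3 markers detected in 10% of its nuclei, a log2 fold of 1 or more over the other clusters with 20 CPM added to both, an enrichment p under 1e-06 and 20% of the detected markers or a marker among its top 10 genes. These thresholds were set after the data were seen. By them 13 clusters with 11895 nuclei (61.4%) took a name and 11 clusters with 7465 nuclei stayed unnamed, 42.8% of nuclei in F1 water, 43.99% in F1 ethanol and 33.6% in P0. Clusters of 1 class were merged, and no cluster of a class held more markers of another class than of its own among its top 10 genes. Cluster 12 met the thresholds above for somatic gonad, vulva and uterus, with 10 of 42 detected markers up. It stayed unnamed, and its top 10 genes held 0 markers of that class and 1 of another.

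UMI counts were summed per library and class where a library held 20 or more nuclei of the class. Sums were tested with edgeR 4.0.16 (trimmed mean of M-values, filterByExpr, robust quasi-likelihood fit) in R 4.3.3, with every library that held enough nuclei in 1 fit so that the 3 groups shared an estimate of the spread (9 libraries, or 5 for coelomocyte-like nuclei, with P0 replicate 1 alone from P0), and Benjamini-Hochberg adjustment within a class at 0.05. Coelomocyte-like nuclei were tested for ethanol against water only, since too few P0 libraries held enough of them. Numbers of nuclei per class were tested with the edgeR quasi-likelihood test and the library total as offset, beside an exact two-sided permutation test. In all, 31 gene lists and 11 marker lists with at least 5 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over all lists and classes, beside camera with an estimated correlation and fry.

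Genes named in the text were those with the largest rise and fall among passing genes in the largest classes (5 each where 956 genes met the rule in epidermis-like nuclei), the 3 with the smallest p where none passed, the 2 with the smallest p that passed in other classes, the 3 members with the smallest p of each described list and passing members of the alcohol list. Which lists to describe was chosen after their values were seen. Differences of a change between classes were tested as an interaction for epidermis-like against intestine-like and body wall muscle-like nuclei, pairs also chosen after the data were seen. CPM values are means ± SD over libraries, n being 5 for P0 and 2 for each F1 group. For single genes in comparisons of groups they use totals of the tested genes adjusted by the trimmed mean of M-values, and for genes across the classes of P0, for *fog-1* and sperm genes, for sums over lists, and for ratios and floors they use the plain total of the class. Where a group held 0 UMIs, a fold is given against a floor of 3 counts over the group, and where it held 1 to 3 UMIs, a ratio with an exact 95% interval. Intervals and floors cover counting error only.

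The edgeR step was tested on simulated counts with 200 changed genes per comparison and class. For F1 ethanol against F1 water 4-fold changes were recovered in 3.03% (neuron-like) to 65.2% (body wall muscle-like) of genes, and for F1 water against P0 in 43.9% to 74.2%. For 2-fold changes the shares were 0 to 5.97% and 1.49% to 16.4%. Alternatives were DESeq2 1.42.0 and its size factors, no low-count filter, the replicate number as a block, a fit of only the 2 groups compared, removal of doublets, at least 500 genes per nucleus, Leiden resolution 2 (38 clusters), thinning of each class to its smallest library, shares among nuclei outside the germline-like class and leaving out each library. Leaving out P0 replicates 1 and 5 together was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.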

Results

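Single-nucleus RNA was counted in 9 droplet libraries from whole adult *Caenorhabditis elegans* of strain JK560, which carries the q253 allele of *fog-1*, a gene needed for germ cells to become sperm. Per the labels, 5 libraries came from P0 animals without exposure, 2 from F1 animals of a water group and 2 from F1 animals of a 0.05% ethanol group. The labels do not say whether the F1 animals themselves or their parents met the ethanol. Total counts ranged from 4021796 unique molecular identifiers (UMIs) in P0 replicate 5 to 10729660 UMIs in F1 ethanol replicate 2. After filtering, a library held 1116 to 3411 nuclei, and the median depth ranged from 747.5 UMIs per nucleus in P0 replicate 5 to 2108 in P0 replicate 1. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Counts of every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom between 9.61 and 99.8.

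The P0 libraries describe the unexposed adult and give the background for both F1 groups. Germline-like, epidermis-like and intestine-like nuclei were the most frequent named classes. Shares are means ± SD over libraries (P0, n = 5). Germline-like nuclei made up 18.5% ± 3.55 of P0 nuclei, epidermis-like nuclei 19.5% ± 9.08 and intestine-like nuclei 15.6% ± 5.46. Pharynx-like nuclei made up 5.297% ± 2.48 (1.64% with clusters at Leiden resolution 2), body wall muscle-like nuclei 4.01% ± 3.55, neuron-like nuclei 2.73% ± 1.07 and coelomocyte-like nuclei 0.730% ± 0.395. The remaining 33.6% ± 12.7 lay in clusters that stayed unnamed. P0 replicate 5 stood apart, with 54.99% of its nuclei unnamed, and 38.1% of its nuclei lay in the unnamed cluster 7. P0 replicate 1 held the largest share of body wall muscle-like nuclei among the P0 libraries, 10.1%.

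**Figure D1:**
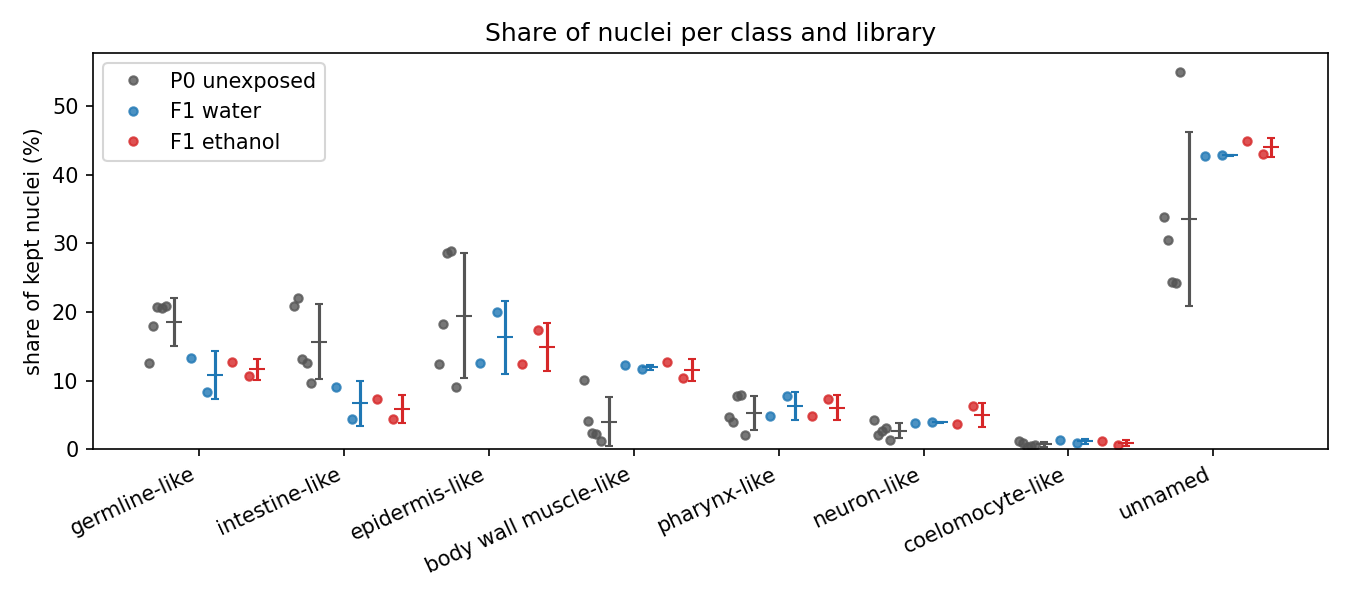
Share of kept nuclei (%) in each class, with 1 point per library for P0 unexposed (n = 5), F1 water (n = 2) and F1 ethanol (n = 2) and with bars for the mean and SD. Body wall muscle-like nuclei averaged 4.01% in P0, 11.97% in F1 water and 11.6% in F1 ethanol.

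Genes of the alcohol and aldehyde list, which takes in every *alh* gene by its name, were counted in several classes rather than in 1 of them. Free RNA was not separated from the RNA of the nuclei, so counts in a class do not show expression there. Levels here are in CPM, the UMI count scaled to the total of the class in a library, as mean ± SD over the P0 libraries (n = 5). *sodh-1*, which encodes an alcohol dehydrogenase, stood at 1080 ± 750 CPM in pharynx-like nuclei, 298 ± 274 in intestine-like nuclei and 43.5 ± 20.9 in germline-like nuclei. Its log2 ratio of pharynx-like nuclei to the mean of the other classes was 2.96 (SE 0.33; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 5.96e-07). The aldehyde dehydrogenase gene *alh-9* was highest in epidermis-like nuclei, 788 ± 202 CPM, and *alh-12* and *alh-13* were highest in intestine-like nuclei, 275 ± 37.8 and 94.5 ± 30.0 CPM. *ctl-2*, which encodes a peroxisomal catalase, reached 285 ± 40.4 CPM in intestine-like nuclei. *alh-8*, the methylmalonate semialdehyde dehydrogenase gene, averaged 884.5 to 1248 CPM in the somatic classes with enough nuclei and 324.5 ± 100.2 CPM in germline-like nuclei. Summed over the list, the level was 1817 ± 258 CPM in germline-like nuclei and 5137 ± 1497 in pharynx-like nuclei. Classes were built from the same counts, so these p-values are too small and serve only as a ranking.

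**Figure D2:**
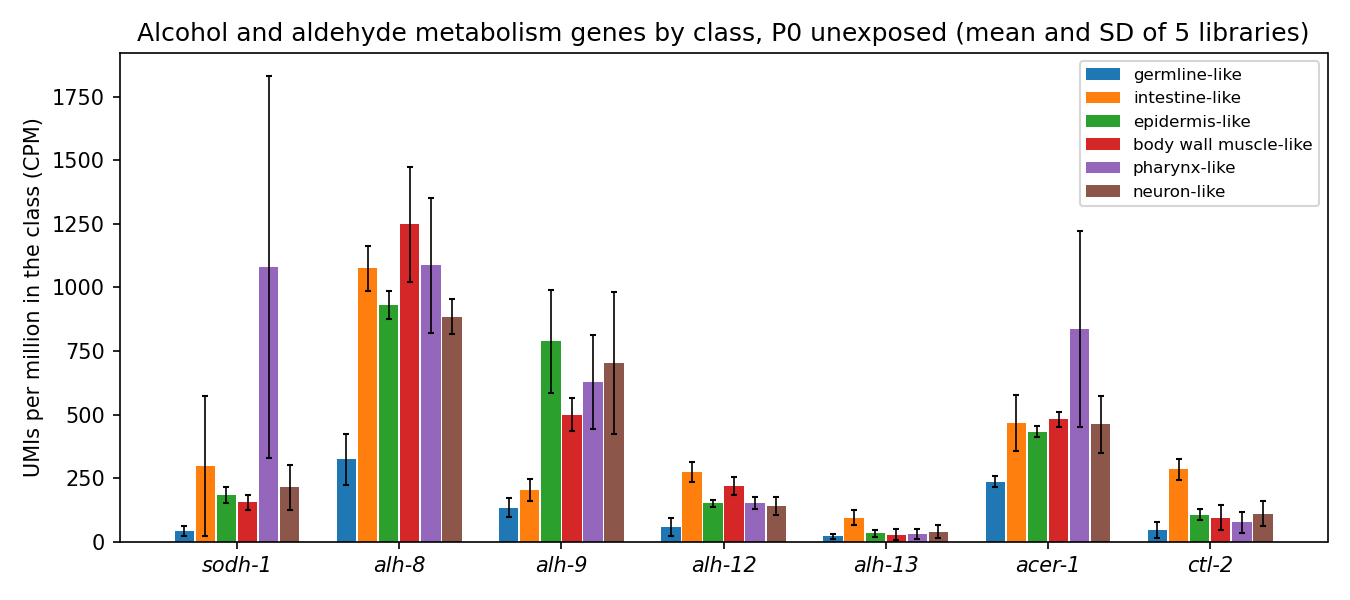
Level of 7 genes of the alcohol and aldehyde list (CPM) in 6 classes of P0 unexposed nuclei, with bars from 0 for the mean and error bars for the SD of 5 libraries. *sodh-1* averaged 1080 CPM in pharynx-like nuclei and 43.5 CPM in germline-like nuclei.

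Gene lists for yolk, muscle and neuropeptides peaked in the matching classes. Those classes were named in part from the same genes, so the peaks are no separate test of the names. Transcripts of the vitellogenins, the yolk proteins, summed to 102200 ± 5452 CPM in intestine-like nuclei and still to 19330 ± 7298 CPM in germline-like nuclei (n = 5). In epidermis-like, body wall muscle-like, pharynx-like and neuron-like nuclei their means lay between 30630 and 36610 CPM. Muscle contraction genes summed to 80240 ± 11590 CPM in body wall muscle-like nuclei and neuropeptide genes to 29470 ± 8398 CPM in neuron-like nuclei. Late oogenesis genes did not mark a class, with 22140 ± 5338 CPM in germline-like, 20560 ± 12150 in pharynx-like and 19890 ± 6603 in epidermis-like nuclei. *fog-1* itself was counted in germline-like nuclei of all 9 libraries, at 63.3 ± 16.6 CPM in P0 (285 UMIs), 59.7 ± 0.291 in F1 water (58 UMIs) and 63.1 ± 21.5 in F1 ethanol (55 UMIs). UMI counts do not read the allele. Transcripts of the major sperm protein family were rare, with 124 UMIs over all P0 nuclei (4.16 ± 5.59 CPM), 179 in F1 water (11.19 ± 10.2 CPM) and 117 in F1 ethanol (11.6 ± 13.2 CPM).

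F1 ethanol was compared with F1 water to see how nuclei of the 2 groups differed, the question of an alcohol response across generations that the series poses. Levels of single genes from here on are CPM with the class totals adjusted by the trimmed mean of M-values, so P0 means differ slightly from those across classes. Some genes of the alcohol and aldehyde list lay close together in both groups, and others, such as *acs-19* in intestine-like nuclei at 311 ± 118.8 CPM with ethanol and 487 ± 40.9 with water, lay apart without passing the test. Body wall muscle-like nuclei made up 11.6% ± 1.62 of F1 ethanol and 11.97% ± 0.365 of F1 water nuclei (n = 2 each). *sodh-1* stood at 392 ± 102 CPM in epidermis-like nuclei of F1 ethanol and 341 ± 152 of F1 water, a log2 difference of 0.20 (SE 0.31). In pharynx-like nuclei *sodh-1* stood at 1552 ± 594 and 1557 ± 375 CPM. *alh-13* in epidermis-like nuclei stood at 105.2 ± 0.861 CPM with ethanol and 101 ± 7.08 with water.

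No class share passed the test. The largest log2 differences were 0.35 (SE 0.60) for neuron-like and -0.33 (SE 0.67) for coelomocyte-like nuclei, and the edgeR quasi-likelihood test on numbers of nuclei with Benjamini-Hochberg adjustment gave an adjusted p of 0.947 for each class. With 6 splits of 4 libraries, an exact permutation test cannot give a p below 0.333.

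Among single genes, *F55G11.4* in coelomocyte-like nuclei was the 1 gene that passed the test of ethanol against water. It fell from 43 UMIs in F1 water to 3 in F1 ethanol, a ratio of 0.0964 with a 95% counting interval of 0.0191 to 0.301. Its fitted log2 change was -3.78 (SE 0.85; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0140). The level was 757.5 ± 868.7 CPM in F1 water and 47.9 ± 20.3 in F1 ethanol, and *F55G11.4* is also among the leading genes of the intestine-like cluster 15. The call was lost without F1 ethanol replicate 1 (adjusted p = 0.998), F1 ethanol replicate 2 (adjusted p = 1) and F1 water replicate 2, where the log2 change was -1.48. Without P0 replicate 1, the 1 P0 library in this fit, the gene fell below the low-count filter and was not tested, and edgeR called 0 genes, beside 8 at an unadjusted p under 0.05; DESeq2 called 0 with all 5 libraries.

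In the other classes the genes with the smallest p did not pass. In epidermis-like nuclei these were *W03F8.6*, at 134 ± 54.7 CPM in F1 water and 14.9 ± 1.99 in F1 ethanol (n = 2 each), *piit-1*, at 92.9 ± 61.2 and 11.4 ± 5.34, and *pqn-71*, at 45.2 ± 31.8 and 5.28 ± 2.07. P0 libraries held 6.19 ± 4.10 CPM of *W03F8.6*, whose log2 difference was -3.11 (SE 0.51; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.685). In germline-like nuclei, *fln-1*, a filamin gene, stood at 1823 ± 616 CPM with water and 646.5 ± 138 with ethanol, *spd-1* at 117 ± 12.24 and 56.96 ± 24.7, and *C16A3.2* at 6.99 ± 1.03 and 29.8 ± 4.96. In intestine-like nuclei, *Y63D3A.7* stood at 38.2 ± 3.85 CPM with water and 93.2 ± 2.14 with ethanol, *hrpf-1* at 48.3 ± 15.3 and 15.7 ± 4.55, and *rod-1* at 101 ± 30.4 and 46.1 ± 15.1. Each of these had an adjusted p of 1 by edgeR, except *W03F8.6*.

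The edgeR quasi-likelihood test called 0 genes in germline-like, intestine-like, epidermis-like, body wall muscle-like, pharynx-like and neuron-like nuclei and in the sum of all nuclei. At an unadjusted p under 0.05 these held 47, 187, 144, 66, 135, 82 and 27 genes. These were 0.602%, 2.55%, 1.46%, 0.819%, 1.69%, 1.83% and 0.1965% of the tested genes, each below the share of 0.05 that no difference would give. The test thus ran below its nominal level, and 0 calls do not show that the groups were alike. DESeq2 called 2 genes in epidermis-like nuclei and 0 in the others. Without F1 ethanol replicate 1, edgeR called 2 genes in intestine-like, 1 in epidermis-like, 6 in body wall muscle-like and 1 in neuron-like nuclei. With no low-count filter it called 1 in intestine-like, 86 in epidermis-like, 2 in body wall muscle-like, 7 in pharynx-like and 12 in neuron-like nuclei. In simulated data of the same depth, 4-fold changes were recovered in 65.2% of genes in body wall muscle-like nuclei, 45.5% in epidermis-like, 19.7% in germline-like and 3.03% in neuron-like nuclei.

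Ribosomal protein genes were the list with the smallest p for ethanol against water: in germline-like nuclei 2 of 81 members had a positive log2 difference, and the median was -0.68. Camera with a preset correlation gave an adjusted p of 3.18e-20, and the adjusted p = 0.995 with an estimated correlation. *rpl-12* stood at 3934 ± 693 CPM with water and 2110 ± 245 with ethanol, and *rps-1* at 2940 ± 1627 and 1505 ± 184 (n = 2 each), and 0 members passed alone or adjusted over the list alone by edgeR; the nominal count for the class was 47, and DESeq2 also called 0. The summed level was 203200 CPM in F1 water replicate 1 and 96600 in F1 water replicate 2, against 105600 and 87450 in the ethanol libraries. Without F1 water replicate 1 the direction of the list turned, with an adjusted p of 0.791.

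Genes of muscle contraction went opposite ways in intestine-like and epidermis-like nuclei, a difference between classes that was not itself tested. In intestine-like nuclei 35 of 39 members were higher with ethanol (median log2 difference 0.60, camera adjusted p = 5.36e-11), and in epidermis-like nuclei 1 of 40 was (median -0.36, adjusted p = 1.06e-10). With an estimated correlation these and the other gene lists that passed had an adjusted p = 0.995. Body wall muscle markers, which share genes with the muscle contraction list, moved with it, with 41 of 49 higher in intestine-like nuclei and 6 of 63 higher in epidermis-like nuclei. Whether these muscle transcripts came from the nuclei of the 2 classes or from free RNA was not tested. In body wall muscle-like nuclei 39 of 43 nuclear genes of oxidative phosphorylation were higher (median 0.17, adjusted p = 5.93e-04), and in pharynx-like nuclei all 14 mitochondrially encoded genes were (median 0.28, adjusted p = 0.0104). In epidermis-like nuclei 56 of 75 genes of fatty acid and lipid metabolism (median 0.16, adjusted p = 1.75e-03) were higher. Camera passed 22 of 224 combinations of list and class, 9 higher and 13 lower with ethanol. Of the lists named here, edgeR called 0 members over all genes or adjusted over the list alone, beside the nominal counts and DESeq2 counts given for each class. Among the marker lists of other classes, 21 of 72 passed, 10 higher and 11 lower, and 0 passed with an estimated correlation or by fry. Without F1 ethanol replicate 1, 76 combinations of list and class passed, and without F1 water replicate 2, 43 passed.

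The lists closest to the series' question did not pass. Of the alcohol and aldehyde list, 9 of 17 members were higher with ethanol in intestine-like nuclei (median 0.01, mean -0.18, camera adjusted p = 0.774) and 12 of 18 in epidermis-like nuclei (median 0.06, adjusted p = 0.600). Without F1 ethanol replicate 1 both turned direction, with adjusted p of 0.868 and 0.792. In intestine-like nuclei, *acs-19* had a log2 difference of -0.65, *alh-1* 0.31, and *ctl-1*, a catalase gene, had 18 UMIs with water and 1 with ethanol, a ratio of 0.0779 with a 95% counting interval of 0.00187 to 0.493, while without F1 water replicate 1 its log2 difference turned to 2.81. In epidermis-like nuclei, log2 differences were 0.26 for *ctl-2* and 0.20 for *alh-10*, and *alh-11* had no clear direction, with a fitted -0.18 (SE 0.28) but 38.15 CPM with ethanol and 35.03 with water over summed UMIs. Small RNA pathway genes in germline-like nuclei had a median of -0.04, with 25 of 55 positive (adjusted p = 0.724), and *glh-1*, *hrde-1* and *alg-1* had log2 differences of -0.72, 0.48 and 1.06, that of *hrde-1* turning to -0.14 without F1 ethanol replicate 1. Genes of histone methylation and heterochromatin had a median of 0.01 and a mean of -0.04, with 24 of 43 positive (adjusted p = 0.502, and 0.0467 without F1 ethanol replicate 1). Among them *wdr-5.3*, *lin-61* and *utx-1* had log2 differences of -0.62, -0.69 and -0.91. Neuropeptide genes in neuron-like nuclei had a median of 0.17, with 52 of 88 positive (adjusted p = 0.288), which became 0.00393 without F1 ethanol replicate 1 and 0.0228 without F1 water replicate 1. Here *flp-11* stood at 119.2 ± 38.9 CPM with water and 1054 ± 676 with ethanol, *flp-21* at 22.5 ± 17.4 and 154 ± 73.8, and *ins-29* at 22.4 ± 4.37 and 104.5 ± 5.59 (n = 2 each).

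F1 water was compared with P0, groups that differ in generation and in being labelled unexposed or water. The labels name no batch, so a batch that differed between P0 and F1 would not be told apart from these. In every named class compared most collagen and cuticle genes were higher in F1 water, a list that passed camera but not with an estimated correlation (adjusted p = 0.658), and of which 0 members passed over all genes in germline-like nuclei. Epidermis-like nuclei held the most called genes, among them *nspb-12*, *nspb-11*, *fipr-6* and *col-90*, which rose, and *dct-8*, *tag-120* and *cnc-6*, which fell. Body wall muscle-like nuclei made up 11.97% ± 0.365 of F1 water nuclei (n = 2) and 4.01% ± 3.55 of P0 nuclei (n = 5), a 2.98-fold difference. In both epidermis-like and body wall muscle-like nuclei *sodh-1* rose.

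Of the classes, body wall muscle-like nuclei passed the test of shares, with a log2 change of 1.57 (SE 0.50; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0226). The exact permutation test gave p = 0.0476, the smallest that 21 splits allow. Intestine-like nuclei made up 6.72% ± 3.302 of F1 water nuclei against 15.6% ± 5.46 in P0 (log2 -1.22, SE 0.54, edgeR adjusted p = 0.111), and germline-like nuclei 10.8% ± 3.49 against 18.5% ± 3.55 (log2 -0.78, SE 0.51, edgeR adjusted p = 0.360). The muscle call was lost without P0 replicate 3 (adjusted p = 0.0633), P0 replicate 4 (0.0744), P0 replicate 5 (0.0880), F1 water replicate 1 (0.136) or F1 water replicate 2 (0.221). It was also lost with clusters at Leiden resolution 2 (log2 change 1.304, adjusted p = 0.0749), where intestine-like nuclei passed (-1.51, adjusted p = 0.0422). Without P0 replicate 1 the muscle log2 change was 2.29. Cluster 8 (*unc-54*, *unc-27*) held most body wall muscle-like nuclei in both groups, and cluster 2 (*lipl-5*, *mtl-1*) held most intestine-like nuclei. Germline-like nuclei of P0 lay in clusters 5 (*neg-1*, *pos-1*; 884 nuclei), 3 (*set-24*, *chk-2*; 559) and 19 (*fem-3*, *mom-2*; 329), and those of F1 water in cluster 3 (350 nuclei), cluster 5 (153) and cluster 19 (5). P0 replicate 1 held 46 nuclei in cluster 5, 230 in cluster 3 and 0 in cluster 19. The unnamed cluster 1 shares the leading genes *rpl-11.1* and *iff-1* with cluster 3, though 2 of 126 detected germline markers were up in it. It made up 4.26% ± 1.44 of P0 and 14.49% ± 0.962 of F1 water nuclei. The lower germline-like share in F1 water was therefore not separated from the naming of clusters.

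In epidermis-like nuclei the genes below were picked by fitted log2 change, and counts of 0 leave their order unmeasured. *nspb-12*, *nspb-11* and *nspb-8* had 580, 486 and 183 UMIs in F1 water and 0 in P0. Against a floor of 3 counts over the P0 group these were at least 297-fold, 249-fold and 93.8-fold higher (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 4.38e-04, 5.48e-05 and 8.34e-03). *fipr-6* had 663 UMIs against 2, a ratio of 510 with a 95% counting interval of 141 to 4219, and *F30H5.3* had 371 against 2, a ratio of 285 (78.4 to 2365). *nspb* and *fipr* genes belong to families with similar members, whose reads the counting could split. Falls were in *F35A5.8*, with 123 UMIs in P0 and 0 in F1 water, at least 26.7-fold lower, and *tap-1*, with 111 and 1 UMIs, a ratio of 0.0139 (0.000348 to 0.0788). *dct-8* fell from 903 ± 421 CPM in P0 (n = 5) to 52.2 ± 11.7 in F1 water (n = 2), a log2 change of -4.12 (SE 0.65). *cnc-6*, an antimicrobial caenacin gene, fell from 64.7 ± 36.4 to 3.17 ± 1.94 CPM and *tag-120* from 33.8 ± 9.39 to 1.96 ± 1.50 CPM. Most epidermis-like nuclei of P0 lay in cluster 0 (1805 nuclei), of which *dct-8* is a leading gene. Most of F1 water lay in clusters 9 (*col-161*, *col-162*; 483 nuclei) and 13 (*sqt-3*, *rol-8*; 211 nuclei). For all calls in this class, the mix of clusters and the levels within them were not separated. Cluster 0 took its name with 13 of 260 detected markers up, against 86 and 84 for clusters 9 and 13, and collagens are among these markers. With F1 water replicate 2 left out, the adjusted p became 0.0685 for *F35A5.8*, 0.0965 for *tap-1*, 0.0781 for *dct-8* and 0.117 for *cnc-6*, and with F1 water replicate 1 left out, 0.0820 for *cnc-6*.

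Members of the alcohol and aldehyde list went both ways in epidermis-like nuclei, with 2 up and 2 down of 18. The list takes in every *alh* gene by its name, and whether each acts on alcohol or its products was not examined. *sodh-1* rose from 184 ± 20.3 to 341 ± 152 CPM (log2 0.89, SE 0.25, edgeR adjusted p = 0.0456) and *alh-13* from 34.3 ± 13.2 to 101 ± 7.08 CPM (log2 1.63, SE 0.29, edgeR adjusted p = 5.76e-03). *ctl-1* fell from 34.2 ± 11.8 to 7.61 ± 3.27 CPM (log2 -2.28, SE 0.44) and *alh-9* from 781 ± 166 to 370 ± 52.3 CPM (log2 -1.08, SE 0.29). In body wall muscle-like nuclei *sodh-1* rose from 151 ± 33.6 to 386 ± 42.2 CPM (log2 1.32, SE 0.28, edgeR adjusted p = 0.0103). F1 ethanol levels lay beside those of F1 water, as with *alh-9* at 370.4 ± 111 CPM. The list had a median of 0.20 in epidermis-like nuclei (12 of 18 positive, camera adjusted p = 0.833). In intestine-like nuclei 14 of 17 members were higher in F1 water (median 0.26, camera adjusted p = 0.0358), with an adjusted p = 0.658 with an estimated correlation. Each of these calls was lost without F1 water replicate 2, where the edgeR adjusted p was 0.661 for *sodh-1* in epidermis-like and 0.295 in body wall muscle-like nuclei, 0.0624 for *alh-13*, 0.160 for *ctl-1* and 0.3002 for *alh-9*. The calls of *sodh-1* in body wall muscle-like nuclei and of *alh-9* were also lost without F1 water replicate 1 (0.0565 and 0.0963), those of *sodh-1* and *alh-9* in epidermis-like nuclei without any of P0 replicates 2 to 5 (0.0648 to 0.111), and that of *sodh-1* there without F1 ethanol replicate 2 (0.0514).

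Collagen and cuticle genes were higher in F1 water for 115 of 130 tested members in epidermis-like nuclei, with a median log2 change of 3.43. Of these 32 rose and 2 fell, and 44 rose and 3 fell adjusted over the list alone. Clusters 9 and 13, which held most epidermis-like nuclei of F1 water but few of P0, were named in part by collagens. The rise was therefore not separated from the mix of clusters. *col-90* rose from 1.73 ± 2.83 to 168 ± 58.5 CPM (log2 6.92, SE 0.61, edgeR adjusted p = 4.38e-04) and *col-89* from 1.50 ± 1.60 to 31.3 ± 3.42 CPM. *col-152* had 159 UMIs against 1, a ratio of 245 with a 95% counting interval of 43.3 to 9720. Summed over the list, the level moved less, from 112500 ± 20920 CPM in P0 to 146300 ± 28780 in F1 water and 123400 ± 6220 in F1 ethanol. The list passed camera with an adjusted p of 3.20e-23, which became an adjusted p = 0.658 with an estimated correlation. With the 1 member at 0 set at its bound, the median was also 3.43. Moulting genes other than collagens, 2 of the 31 being also members of the list, moved with it. They summed to 494.6 ± 154 CPM in P0 and 1665 ± 171 in F1 water, and P0 replicate 1 held 768 CPM of them.

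The same list was higher in the other classes. In body wall muscle-like nuclei 81 of 84 members were higher (median 1.89, camera adjusted p = 2.39e-46), with 34 that rose and 68 that rose adjusted over the list alone. With an estimated correlation the list had an adjusted p = 0.658 in this class and in those that follow. *col-139* rose from 175 ± 70.5 to 1793 ± 923 CPM, *col-147* from 5.76 ± 8.85 to 311 ± 124 CPM (log2 4.72, SE 0.46, edgeR adjusted p = 2.52e-06) and *col-13* from 1.72 ± 3.85 to 137 ± 30.9 CPM. In intestine-like nuclei 66 of 70 were higher (median 2.17, 7 rose, 49 rose and 2 fell adjusted over the list alone), in pharynx-like nuclei 84 of 90 (median 2.54, 17 rose, 45 rose and 1 fell adjusted over the list alone) and in neuron-like nuclei 51 of 59 (median 1.44, 9 rose, 31 adjusted over the list alone). In germline-like nuclei 79 of 83 were higher (median 3.46), and edgeR called 0 members over all genes and 65 adjusted over the list alone, beside a nominal count of 904 for the class and 80 genes by DESeq2. There *col-130* had 42 UMIs in F1 water and 1 in P0, a ratio of 188 with a 95% counting interval of 31.9 to 7600, and *col-13* had 52 and 2 (edgeR adjusted p = 0.0620 for both). Epidermis markers, which include most genes of the collagen and cuticle list and so are no separate evidence, moved with it. In body wall muscle-like nuclei 124 of 135 of these markers were higher, of which 41 rose and 1 fell.

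**Figure D3:**
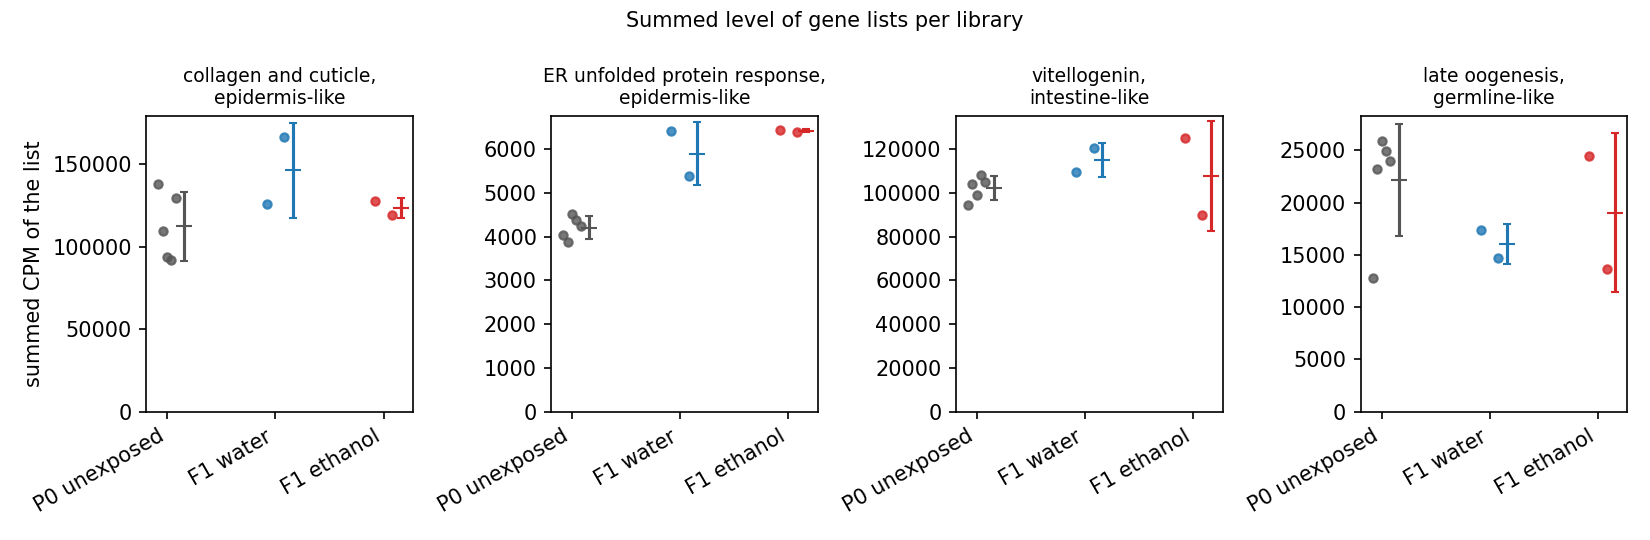
Summed level of 4 gene lists (CPM, axes from 0) in the named class, with 1 point per library for P0 unexposed (n = 5), F1 water (n = 2) and F1 ethanol (n = 2) and with bars for the mean and SD. Collagen and cuticle genes in epidermis-like nuclei averaged 112500 CPM in P0, 146300 in F1 water and 123400 in F1 ethanol, and late oogenesis genes in germline-like nuclei 22140, 16050 and 19030.

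Genes for muscle contraction, basement membrane and protein folding were also higher in epidermis-like nuclei of F1 water. For muscle contraction 38 of 40 members were higher and 16 rose (25 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 2.01e-10, and adjusted p = 0.718 with an estimated correlation). Among them *myo-2*, a pharyngeal myosin, rose from 17.3 ± 12.8 to 322 ± 117 CPM, *tnc-2* from 16.21 ± 12.21 to 174 ± 11.8 and *tni-3* from 89.01 ± 16 to 229 ± 35.2. Pharynx markers moved with them, 35 of 35 higher (median 2.87, 22 rose), as did body wall muscle markers, 60 of 63 higher (median 0.79, 19 rose). Both marker lists share genes with the muscle contraction list. Whether these muscle and pharynx transcripts came from epidermis-like nuclei themselves, from free RNA or from other cells was not tested. For the basement membrane 17 of 21 were higher and 3 rose (12 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 3.41e-03, and adjusted p = 0.658 with an estimated correlation). These were *unc-52*, the perlecan gene, which rose from 173.5 ± 59.8 to 432 ± 4.27 CPM, *him-4* (log2 0.69) and *pat-2* (log2 0.81). For the unfolded protein response of the endoplasmic reticulum 16 of 22 were higher and 4 rose (5 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.0397, and adjusted p = 0.658 with an estimated correlation). The disulfide isomerase genes *pdi-2* and *pdi-6* rose by 1.32 and 1.15 on the log2 scale and the chaperone gene *hsp-3* by 0.99. The list's call was lost without P0 replicate 1 (0.157), 2 (0.0703) or 5 (0.0601), F1 ethanol replicate 1 (0.0905) or 2 (0.0634), or F1 water replicate 1 (0.351). Single calls were lost without F1 water replicate 2 (*unc-52*, *him-4*, *pat-2*, *pdi-2* and *hsp-3*, 0.103 to 0.399), without F1 water replicate 1 (*unc-52*, *him-4*, *pat-2*, *pdi-6* and *hsp-3*, 0.0596 to 0.122), without P0 replicate 2, 4 or 5 (*him-4* and *pat-2*, 0.0861 to 0.116), without P0 replicate 3 (*him-4*, 0.108) and without P0 replicate 4 (*hsp-3*, 0.0540).

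Genes of propionate breakdown and the methionine cycle were higher in both epidermis-like and body wall muscle-like nuclei. In body wall muscle-like nuclei 17 of 22 were higher and 3 rose (11 rose and 1 fell adjusted over the list alone), with a median of 0.83 (camera adjusted p = 2.66e-03, and adjusted p = 0.658 with an estimated correlation). *metr-1*, the methionine synthase gene, rose from 139 ± 67.4 to 454 ± 124 CPM, *ahcy-1* from 477 ± 159 to 1226 ± 108 and *mel-32* from 323.5 ± 93.5 to 681.5 ± 90.2. In epidermis-like nuclei 16 of 22 were higher and 3 rose (8 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.0379, and adjusted p = 0.805 with an estimated correlation). There *metr-1* rose from 194 ± 42.7 to 457 ± 94.8 CPM, *sams-3* by 1.09 and *mtrr-1* by 0.73 on the log2 scale. The epidermal list was lost without P0 replicate 3 (0.0571) or 4 (0.0695), F1 ethanol replicate 1 (0.0826) or 2 (0.0667), or F1 water replicate 2 (0.409). All 6 single calls were lost without F1 water replicate 2 (0.157 to 0.650), those of *ahcy-1*, *mel-32* and *sams-3* without F1 water replicate 1 (0.0878 to 0.171), those of *mel-32*, *sams-3* and *mtrr-1* without P0 replicate 2, 3 or 4 (0.0634 to 0.161), those of *mel-32* and *mtrr-1* without P0 replicate 5 (0.0736 and 0.0895), and those of *sams-3* and *mel-32* without F1 ethanol replicate 2 (0.0547 and 0.0658), with *sams-3* also lost without F1 ethanol replicate 1 (0.0508).

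Germline-like nuclei of F1 water held lower levels of meiotic and oogenesis genes as lists, while no gene passed alone. The class was made up of different clusters in the groups, with 329 nuclei of cluster 19 in P0 and 5 in F1 water, so the mix of clusters and the levels within them were not separated. Late oogenesis genes did not mark this class in P0, with 22140 ± 5338 CPM here and 20560 ± 12150 in pharynx-like nuclei. Their fall was therefore not shown to be particular to germline-like nuclei. Of the late oogenesis list 4 of 40 members were higher (median -0.49, camera adjusted p = 8.38e-04, and adjusted p = 0.907 with an estimated correlation), and of the meiotic prophase list 11 of 43 (median -0.27, camera adjusted p = 0.0259, and adjusted p = 0.658 with an estimated correlation). *chs-1*, which makes eggshell chitin, stood at 755 ± 372 CPM in P0 (n = 5) and 269 ± 43.3 in F1 water (n = 2), *puf-5* at 931 ± 400.3 and 389 ± 76.1, and the yolk receptor gene *rme-2* at 526 ± 135 and 301 ± 8.88. *syp-4*, of the synaptonemal complex, stood at 386 ± 101 and 196 ± 19.9 CPM, *spo-11* at 207 ± 64.3 and 97.7 ± 45.1, and *cosa-1* at 67.1 ± 5.35 and 42.04 ± 11.4. Their edgeR adjusted p ranged from 0.363 to 0.426. Both list calls were lost without F1 water replicate 2, with camera adjusted p of 0.0886 for late oogenesis and 0.0508 for meiotic prophase. The summed late oogenesis level was 12760 CPM in P0 replicate 1, below the F1 water mean of 16050 ± 1913.

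In intestine-like nuclei *tag-120* fell from 366 UMIs in P0 to 2 in F1 water, a ratio of 0.0177 with a 95% counting interval of 0.00213 to 0.0642, and *col-149* rose from 5 to 47 UMIs (log2 4.89, SE 0.62, edgeR adjusted p = 3.06e-03). The vitellogenin gene *vit-1* stood at 2692 ± 574 CPM in P0 and 6593 ± 2058 in F1 water (edgeR adjusted p = 0.0620), *vit-4* at 8843 ± 3843 and 14000 ± 883, and *vit-6* at 31270 ± 4003 and 39640 ± 6677, and the list did not pass (5 of 6 higher, camera adjusted p = 0.121). Heat shock genes had a median of -0.01 with 8 of 16 higher (camera adjusted p = 0.627), while *hsp-16.2* stood at 91.5 ± 27.2 CPM in P0 and 33.8 ± 10.1 in F1 water, *hsp-16.41* at 85.9 ± 29.3 and 32.3 ± 8.69, and *hsp-70* at 33.5 ± 31.1 and 5.23 ± 0.966, with edgeR adjusted p of 0.0940, 0.130 and 0.283. In pharynx-like nuclei *D1054.8* rose from 50.96 ± 5.09 to 200.3 ± 4.23 CPM (log2 1.97, SE 0.23, edgeR adjusted p = 2.10e-03) and *tag-120* fell by 3.97 on the log2 scale. In neuron-like nuclei *col-77* rose from 1 to 58 UMIs and *F20A1.10*, a leading gene of the unnamed cluster 14, fell from 407 ± 153 to 21.2 ± 8.30 CPM. Of the neuropeptide list there, 22 of 88 members were higher (median -0.64, camera adjusted p = 8.38e-04, and adjusted p = 0.658 with an estimated correlation). The list takes in every *nlp* gene by its name, and some of them, *nlp-28* included, are also epidermis markers. Log2 differences of *nlp-28*, *flp-3* and *flp-11* were -1.77, -3.43 and -2.65 with edgeR adjusted p of 0.188 to 0.243. Over all nuclei *nspb-11* rose from 1 to 561 UMIs and *grd-6* from 3 to 337 UMIs, the latter a ratio of 192 with a 95% counting interval of 65.2 to 937. Calls lost without F1 water replicate 2 had an adjusted p of 0.102 for *D1054.8*, 0.252 for *tag-120* in pharynx-like nuclei, 0.207 for *F20A1.10* and 0.215 for *col-77*.

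By edgeR's quasi-likelihood test, 984 of 9870 genes passed in epidermis-like nuclei (719 up, 265 down), 203 of 8061 in body wall muscle-like (91 of them down), 72 of 7977 in pharynx-like (55 up, 17 down), 45 of 7345 in intestine-like (37 up, 8 down) and 10 of 4475 in neuron-like nuclei (9 up, 1 down). In germline-like nuclei 0 of 7806 passed, beside 904 at an unadjusted p under 0.05 and 80 by DESeq2. Over all nuclei 206 of 13740 passed. Camera passed 65 of 209 combinations of list and class, 36 higher and 29 lower in F1 water, and 40 of 65 for marker lists of other classes, while 0 passed with an estimated correlation, and fry passed 0 gene lists and 1 marker list. Counts moved with single libraries. Without P0 replicate 1 they were 2465 in epidermis-like, 381 in body wall muscle-like, 359 in pharynx-like, 246 in intestine-like, 59 in neuron-like and 886 in germline-like nuclei and 1818 over all nuclei. Without P0 replicates 2, 3 and 4 in turn, epidermis-like nuclei held 535, 470 and 408, intestine-like nuclei 23, 21 and 16 and all nuclei 12, 31 and 21. Body wall muscle-like nuclei held 121 without P0 replicate 2, pharynx-like nuclei 11 and 23 without P0 replicates 3 and 4, and without P0 replicate 5 intestine-like nuclei held 21 and all nuclei 49. Without F1 water replicate 1 the counts were 464 in epidermis-like, 59 in body wall muscle-like, 5 in intestine-like, 18 in neuron-like and 8 in germline-like nuclei and 87 over all nuclei. Without F1 water replicate 2 they were 239, 18 and 6 in epidermis-like, body wall muscle-like and intestine-like nuclei, 6 over all nuclei and 0 in pharynx-like and neuron-like nuclei by edgeR. Germline-like nuclei held 27 and 19 without F1 ethanol replicates 1 and 2, and over all nuclei 107 rose and 12 fell without F1 ethanol replicate 2.

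The neighbouring chromosome X genes *fbxc-37*, *linc-75* and *F31A9.2*, singled out after their values were seen, were counted in each P0 library and in none of the 4 F1 libraries. *fbxc-37* had 8 to 19 UMIs per P0 library, *linc-75* 11 to 34 and *F31A9.2* 31 to 100, together 436 UMIs over the P0 group. The F1 libraries held 0 of 32272812 UMIs, which allows up to 0.0930 CPM at a floor of 3 counts over both F1 groups against 14.9 CPM in P0, at least 160-fold lower. The flanking genes were counted in all 9 libraries, *linc-64* with 2 to 29 UMIs and *C14E2.12* with 98 to 299.

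**Figure D4:**
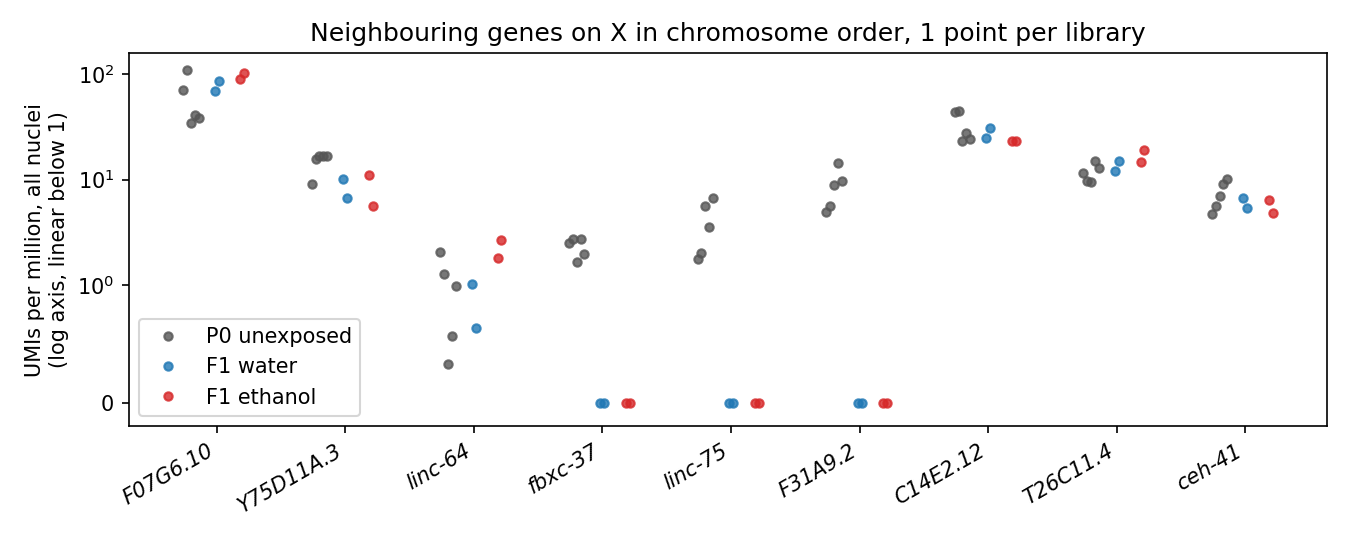
Level over all nuclei (CPM, log axis that is linear below 1) of neighbouring genes on chromosome X in chromosome order, with 1 point per library for P0 unexposed, F1 water and F1 ethanol. *fbxc-37*, *linc-75* and *F31A9.2* had 436 UMIs in the 5 P0 libraries and 0 in the 4 F1 libraries.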

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

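The tests of library depth for the cuticle genes, the tests of free RNA in classes other than body wall muscle-like and at a second floor of counts, both tests of the chromosome X genes, and the pairs of classes compared for a difference of change, were chosen only after the result was seen.

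Cuticle genes that rose in epidermis-like nuclei of F1 water moved together with moulting genes other than collagens. Against library depth as the cause, 81.25% of the called collagen and cuticle members (26 of 32) were still called after thinning. Animals at an earlier developmental stage, or closer to a moult, are a candidate explanation. The 31 moulting genes had a median log2 change of 2.91 (24 of 26 tested positive, 9 rose and 1 fell). Of the 31, 23 were also epidermis markers and 2 were also in the collagen and cuticle list. The summed level of the moulting genes was 768 CPM in P0 replicate 1, 407 to 455 in the other P0 libraries and 1544 to 2635 in F1. *cut-2*, a member of both lists, alone held 457 and 395 CPM in the F1 water libraries. Not every value moved that way. *nhr-23* had a log2 change of -0.38 (SE 0.32), and most vitellogenin genes were higher in intestine-like nuclei of F1 water, though their list did not pass. A larger share of nuclei from clusters 9 and 13 stays open, since the median ratio of cluster 0 over the highest other class was 0.381, within the bound set beforehand for that cause, and it was left undecided only after this value was seen, because clusters 0, 9 and 13 had been split by these same genes and only 6 and 3 genes could be used. Generation and the label unexposed or water differ with the groups, the labels name no batch, and none of these was tested apart from stage.

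The same genes were also higher in germline-like, intestine-like, body wall muscle-like, pharynx-like and neuron-like nuclei, which free RNA could bring. Free RNA from epidermis-like nuclei as the single source was tested on the premise that 1 source keeps its genes in 1 ratio. The ratio was taken to levels in epidermis-like nuclei, a class merged from clusters that differ in collagens. The make-up of free RNA itself was not measured, so a wide spread argues only against free RNA with that merged profile. In body wall muscle-like nuclei the log2 ratio had an SD over collagen and cuticle genes of 2.34 in F1 water replicate 1. It was 1.93 in replicate 2 (at least 10 UMIs in muscle). With at least 30 UMIs in both classes the SDs were 2.17 and 1.88. In pharynx-like nuclei of F1 water they were 1.38 to 1.95 over both floors. There F1 ethanol replicate 1 gave 0.604 with at least 30 UMIs. Free RNA of another make-up stays open in both classes. In germline-like, intestine-like and neuron-like nuclei free RNA from epidermis-like nuclei stays open. The bounds were under 0.5 for this cause and above 1 against it. Over the F1 water libraries with floors of 10 and 30 UMIs, the SD ran from 0.695 in germline-like to 2.07 in intestine-like nuclei. In neuron-like nuclei it ran from 1.002 to 1.906, above the bound against this cause, but the lowest value lay next to that bound. F1 ethanol replicate 1 gave 0.784 in neuron-like nuclei with at least 30 UMIs, which meets neither bound. Free RNA of any source, added as a test after the muscle values, stays open too: the ratio of intestine-like to germline-like levels had an SD of 0.404 and 0.257 in the F1 water libraries with at least 30 UMIs, within the bound for it (though 0.765 in F1 ethanol replicate 2), but 0.747 and 0.625 with at least 10, which meets neither. Expression in body wall muscle-like nuclei themselves was not tested apart from it.

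The chromosome X neighbours *fbxc-37*, *linc-75* and *F31A9.2* had 436 UMIs in P0 and 0 in F1. Depth and the mix of nuclei are argued against, since P0 rates per class predict 399.5 UMIs in the F1 libraries. Of 13443 genes scanned, 4 were counted in all P0 and in no F1 library, and outside the neighbours that prompted the scan only 1 gene was left, *sls-2.8* on chromosome III with 26 UMIs in P0, too few to test whether such genes lie together. A local difference in the DNA of the worms and local silencing both stay open, and DNA was not analysed here.

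Among the 48 series of P0 values tested, 9 held a library far from the other 4 by Dixon's test (critical value 0.71). Chance gives about 1 in 20 for normally spread values. That rate does not hold for counts near 0, so the 9 were not set against it. P0 replicate 1 was high in germline-like nuclei for *col-130* (1.52 CPM), *col-13* (3.04 CPM) and *col-147* (6.08 CPM), in neuron-like nuclei for *col-77* (6.07 CPM), in intestine-like nuclei for *Y63D3A.7* (98.9 CPM) and over all nuclei for *nspb-11* (0.16 CPM). P0 replicate 3 was alone in holding *pqn-71* in epidermis-like nuclei (0.53 CPM), and *tag-120* was high in epidermis-like nuclei of P0 replicate 2 (50.01 CPM) and pharynx-like nuclei of P0 replicate 5 (83.5 CPM). Those of *col-130*, *col-13*, *col-77*, *pqn-71* and *nspb-11* rest on 1 or 2 UMIs against 0.

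The change from P0 to F1 water differed between classes for 89 of 9590 genes between epidermis-like and intestine-like nuclei and for 285 of 10133 between epidermis-like and body wall muscle-like nuclei. Epidermis-like nuclei of P0 and F1 water lay mostly in different clusters, so these differences were not separated from the mix of clusters. *alh-13* changed less in intestine-like nuclei by a log2 difference of -1.43 (SE 0.27, edgeR adjusted p = 5.29e-03) and in body wall muscle-like nuclei by -1.73 (adjusted p = 0.0172). *alh-9* differed the other way, by 1.16 (adjusted p = 9.72e-03) and 1.13 (adjusted p = 3.36e-03). Between body wall muscle-like and epidermis-like nuclei the difference was 1.00 for *dct-8* (edgeR adjusted p = 0.0459) and 3.09 for *col-147* (adjusted p = 7.11e-03), whose separate fits rose by 3.39 in epidermis-like and 4.72 in body wall muscle-like nuclei and so lie closer together, while *sodh-1* differed by 0.44 with an adjusted p of 0.552. The fitted -8.34 for *nspb-12* measures no size, since the gene had 0 UMIs in epidermis-like nuclei of P0 and was not tested in body wall muscle-like nuclei alone.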

How the results depend on the processing

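The alternative that left out P0 replicates 1 and 5 together and the shares in P0 at Leiden resolution 2 were chosen only after the result was seen, and the others were planned. Of 90 gene results named in the text, 45 of which passed the test, 1691 values under 19 settings kept their direction and side of the threshold in 1491 cases, lost the call in 129, gained it in 69 and reversed in 2. The 2 reversals were *hrde-1* in germline-like nuclei, with -0.14 to 0.90 over the libraries left out, and *ctl-1* in intestine-like nuclei, with -6.27 to 2.81, neither of which had passed. The replicate block lost 32 of the 45 calls, leaving out F1 water replicate 2 lost 25 and F1 water replicate 1 lost 11, while no low-count filter gained 16 and leaving out P0 replicate 1 gained 12. Where 1 library of a group was left, it was assumed to vary like the other groups. The cause of changes under the settings below was not tested, except that fewer counts or libraries carry less information. In counts simulated with the fitted spread for these libraries, 2-fold changes were mostly not recovered. Recovery in the real counts was not measured, and depth and number of libraries were not varied.

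For F1 ethanol against F1 water, edgeR with no low-count filter called 1 gene in intestine-like, 86 in epidermis-like, 2 in body wall muscle-like, 7 in pharynx-like and 12 in neuron-like nuclei. DESeq2 called 2 genes and thinning 1 in epidermis-like nuclei. In coelomocyte-like nuclei the 1 call became 0 with DESeq2, no filter, a fit of the 2 groups (where the gene was not tested) or Leiden resolution 2, beside 17 genes at an unadjusted p under 0.05, and 2 with the block. Leaving out single libraries gave 0 to 6 genes in body wall muscle-like, 0 to 2 in intestine-like, 0 to 1 in epidermis-like, neuron-like and coelomocyte-like nuclei and 0 elsewhere. Camera passed 16 to 76 lists with single libraries left out, and 0 with an estimated correlation or by fry.

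For F1 water against P0, counts of called genes are given for germline-like, intestine-like, epidermis-like, body wall muscle-like, pharynx-like and neuron-like nuclei where they moved by over 1.5 times. DESeq2 called 80 in germline-like, 129 in intestine-like, 111 in pharynx-like and 38 in neuron-like nuclei and 896 over all nuclei. No low-count filter gave 396, 279, 2102, 383, 380 and 127 in the 6 classes. Thinning gave 6 in germline-like, 487 in epidermis-like, 54 in body wall muscle-like and 20.0 in pharynx-like nuclei. A fit of the 2 groups gave 16 in germline-like nuclei and 115 over all nuclei, at least 500 genes gave 5 in germline-like nuclei, and Leiden resolution 2 gave 121 in body wall muscle-like nuclei. Without P0 replicates 1 and 5 the counts were 407, 209, 2168, 316, 376 and 54, with 1138 over all nuclei. Leaving out single libraries gave 0 to 886, 5 to 246, 239 to 2465, 18 to 381, 0 to 359 and 0 to 59, with 6 to 1818 over all nuclei, and 47 to 73 gene lists by camera, against 0 with an estimated correlation or by fry. Size factors of DESeq2 and removal of doublets moved no count by over 1.5 times.

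Replicate numbers are shared by the groups, but 2 pairs do not show pairing and the labels name no shared batch. Deviations of F1 water replicate 1 and F1 ethanol replicate 1 correlated across genes with r from 0.20 in neuron-like nuclei to 0.64 over all nuclei. With the replicate block, F1 water against P0 gave 5 genes in intestine-like, 29 in epidermis-like, 67 in body wall muscle-like, 15 in pharynx-like and 0 in neuron-like nuclei and 0 over all nuclei, and the share of body wall muscle-like nuclei had a log2 change of 0.82 (adjusted p = 0.224) and that of epidermis-like nuclei 0.073. Of the described lists, camera under the block gave an adjusted p of 0.0731 for meiotic prophase and 0.436 for late oogenesis in germline-like nuclei, 0.0710 for the basement membrane and 0.290 for propionate and the methionine cycle in epidermis-like nuclei and 0.124 for the latter in body wall muscle-like nuclei, all of which had passed, and it passed 50 lists in all against 65. P0 replicates 3 to 5 have no F1 library of their number, so the block leaves that comparison to replicates 1 and 2.

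Shares in P0 moved by under 1 SD in 63 of 64 alternatives, the exception being pharynx-like nuclei at Leiden resolution 2 (1.64%), where a cluster of 687 nuclei with 15 of 46 pharynx markers up stayed unnamed. With single libraries left out they were 17.97% to 20.04% for germline-like, 14.04% to 17.1% for intestine-like, 17.1% to 22.05% for epidermis-like, 2.49% to 4.71% for body wall muscle-like, 4.64% to 6.08% for pharynx-like, 2.35% to 3.06% for neuron-like, 0.593% to 0.837% for coelomocyte-like and 28.2% to 35.9% for unnamed nuclei. Log2 changes from P0 to F1 water were then 1.34 to 2.29 for body wall muscle-like, -1.83 to -0.79 for intestine-like, -1.15 to -0.48 for germline-like, -0.63 to 0.041 for epidermis-like, -0.14 to 0.55 for pharynx-like, 0.35 to 0.74 for neuron-like, 0.34 to 1.01 for coelomocyte-like and 0.25 to 0.60 for unnamed nuclei. For ethanol against water they were -0.20 to 0.085, -0.63 to 0.41, -0.19 to 0.48, -0.42 to 0.25, -0.39 to 0.33, -0.07 to 0.66, -0.89 to 0.13 and 0.0069 to 0.071 in the same order. Leiden resolution 2 gave 1.304 for body wall muscle-like (adjusted p = 0.0749), -1.51 for intestine-like (adjusted p = 0.0422), 1.16 for pharynx-like (adjusted p = 0.0564, against 0.25 at resolution 1) and 0.30 for epidermis-like nuclei from P0 to F1 water, and 0.16 and 0.038 for body wall muscle-like and pharynx-like nuclei from water to ethanol. Without P0 replicates 1 and 5 the values were -0.87 for germline-like (adjusted p = 0.0443), -1.24 for intestine-like (adjusted p = 0.0220) and -0.070 for pharynx-like nuclei. Pharynx-like nuclei at Leiden resolution 2 and coelomocyte-like nuclei at 500 genes gave no count of called genes.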

Other observations

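The scan for genes present in 1 generation alone was chosen only after the chromosome X genes were seen.

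Unnamed clusters had the leading genes given here, and whether they are kinds of nuclei, nuclei of low depth or marks of 1 library was not tested. Cluster 18 was led by *egl-1*, an activator of programmed cell death, beside *Y46H3C.7* and *elf-1*, and it held 358 nuclei with a median of 1929 UMIs. Cluster 22 was led by *nspc-7*, *nspc-14* and other members of the *nspc* family and held 108 nuclei. Cluster 23 was led by the polyketide synthase gene *pks-1* with the lipid genes *acs-1*, *pod-2* and *acly-1*, and held 81 nuclei. Cluster 12 was led by *fasn-1*, *tbh-1*, *cle-1* and *perm-4* and made up 4.04% ± 0.572 of P0, 3.44% ± 0.60 of F1 water and 3.03% ± 0.844 of F1 ethanol nuclei. In it 10 of 42 detected markers of somatic gonad, vulva and uterus were up. Cluster 7, led by *F55B11.3* and *ule-3*, took 69.9% of its 1114 nuclei from P0 replicate 5. Cluster 1, with a median of 619.5 UMIs and ribosomal protein genes among its leading genes, took most of its 1836 nuclei from F1 libraries.

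In the scan of genes by generation, 11 genes were counted in all 4 F1 libraries and in no P0 library. *M195.2* had 2 to 73 UMIs per F1 library, *AC3.13* 2 to 63 and *F48G7.8* 3 to 81, and *K06H6.1* and *K06H6.2* had 1 to 19 and 4 to 22. These values carry no test.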
